A study of Rattus norvegicus with 18 samples.

How the data were processed

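Ventricular cells of 1-day-old Sprague-Dawley rats were plated briefly so that faster-attaching cells could be removed, moved to collagen-coated plates and treated in low-serum medium, per the labels' protocols. RNA libraries were 3 with DMSO and 3 with blebbistatin (0.5 h). The submitters' processing notes name HISAT2 2.1.0, StringTie 1.3.4, edgeR 3.20.9, Trim Galore, BWA, MACS2 2.1.0 and the rat build rn6 for the RNA and chromatin samples together, without saying which tool made which file. The annotation and the strand setting are not known here. The 12 chromatin immunoprecipitation and input samples are not analysed here. Sirt1 is not analysed here.

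The deposited table holds CPM values made by the authors for 28909 genes in 6 libraries, although its name speaks of counts: each column has the same total. In each library 99.1 to 99.2% of the values above 0 are whole multiples, within 0.02, of a step of 0.0158 to 0.0168 CPM, taken as 1 read, and the rest are fractions of it. Whole reads were therefore not recovered for all genes. The step gives 59.6 to 63.3 M reads per library. A floor of 3 reads lies between 0.0474 and 0.0503 CPM and covers counting error only. An exact 0 is described only as listed at 0. Of the gene names, 17134 matched a RefSeq symbol and 1820 a RefSeq synonym in a newer rat assembly's gene table, used for names and overlaps only. A further 25 names are bare numbers and were kept unnamed.

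The design fixed before the data were examined assumed counts and a count-based test. Because the values are CPM, the test was changed to limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust settings) on log2(CPM divided by a TMM factor + 0.1). It used no block, was two-sided and called genes at a Benjamini-Hochberg adjusted p under 0.05. TMM factors, computed without weights (trims of 0.3 and 0.05), ran from 0.928 to 1.03. Genes entered with at least 0.162 CPM (10 reads at the median depth of 61.7 M) in at least 3 libraries, which left 15204 of 19425 genes above 0 in any library. The added 0.1 CPM understates changes of low genes. Means ± SD are of TMM-scaled CPM, and values of single libraries are CPM as deposited. Genes that overlap or resemble another gene are uncertain, since the way reads were counted is not stated.

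Of 40 gene and marker lists fixed before the data were examined, 38 had at least 5 tested members. They were tested with camera on the same log2 values, with a variance trend in place of the planned voom weights, a preset correlation of 0.01 and adjustment over the 38 lists. Camera with an estimated correlation and fry stand beside it. The other 2 lists had 0 and 4 tested members. The result of 1 tested list is not reported here.

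Named genes followed a rule fixed beforehand. It takes up to 10 genes per direction past the threshold with separated groups, a symbol and a mean log2 CPM of at least 1. Where fewer than 5 passed in a direction, it takes the 5 with the lowest p in it. It adds a fixed set of cardiac, NFAT, histone and cell cycle genes and up to 4 members per list with the lowest p. The other immediate early genes named are the content of the count adjusted over the list alone. That adjustment was made within each list separately, with no adjustment over the lists. It was not among the results fixed beforehand.

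The steps were tested on simulated data for 15204 genes with 200 planted changes, 50 per size. The test recovered 0 of 50 genes at a log2 fold change of 0.5, 10 at 1, 36 at 2 and 38 at 3, and called 87 genes, 3 of them not planted. With nothing planted, limma called 0 genes and camera 0 lists. Simulated genes were independent, which real genes are not. Each simulated gene also had the same spread in every library, while DMSO replicate 1 stood apart in the real data. The recovery and the false calls therefore need not carry over to these libraries. Alternatives covered scaling, the filter, the pseudocount, the threshold, the replicate block, library weights and leaving out each library in turn. The lowest chi-square per degree of freedom between a pair of libraries was 35.3, so no library duplicates another.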

Results

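Neonatal rat ventricular cardiomyocytes were exposed for 0.5 h to blebbistatin, a small molecule that blocks the ATPase of myosin II motors, or to its solvent DMSO, and their RNA was sequenced. The series title links the cytoskeleton to cardiomyocyte cell cycle activity, histone modification and a Sirt1-NFAT axis. The comparison asks which transcripts differed after a short block of myosin II. The treatment protocol gives a dose of 25 µM, while the series' design text also gives 0.25. Of the 18 samples, 6 are RNA libraries, 3 per group. The 6 H3K9me3 chromatin immunoprecipitation samples and 6 inputs are not analysed here. The RNA values are CPM, reads per gene scaled to the same total in every library, and the smallest step between values corresponds to 59.6 to 63.3 M reads per library. The labels do not say that the 3 libraries of a group came from separate cell preparations, so p-values measure only the spread between these libraries.

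DMSO replicate 1 stood apart from the other 5 libraries. Component 1 carried 42% of the variance and placed it at -77.4, against -3.04 to 34.6 for the rest. Cardiomyocyte markers went both ways in it. The natriuretic peptide gene Nppa was at 495 CPM in this library and between 2785 and 5326 CPM in the others. Myl2 was also lowest there (27.24 against 56.9 to 104.6 CPM). In contrast, Myh7 was at 19640 against 11150 to 13110 CPM, Myh6 at 2203 against 1590 to 1644 CPM and Ryr2 at 1201 against 555.8 to 758.5 CPM. The mean log2 level of 30 ribosomal protein genes differed by -1.03 from the mean of the other 5 libraries. The difference was -0.89 for 12 macrophage and leukocyte markers, -0.38 for 15 cardiomyocyte markers and -0.011 for 14 fibroblast markers. The 4 measured red blood cell genes differed the other way, by 1.36 on average.

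**Figure D1:**
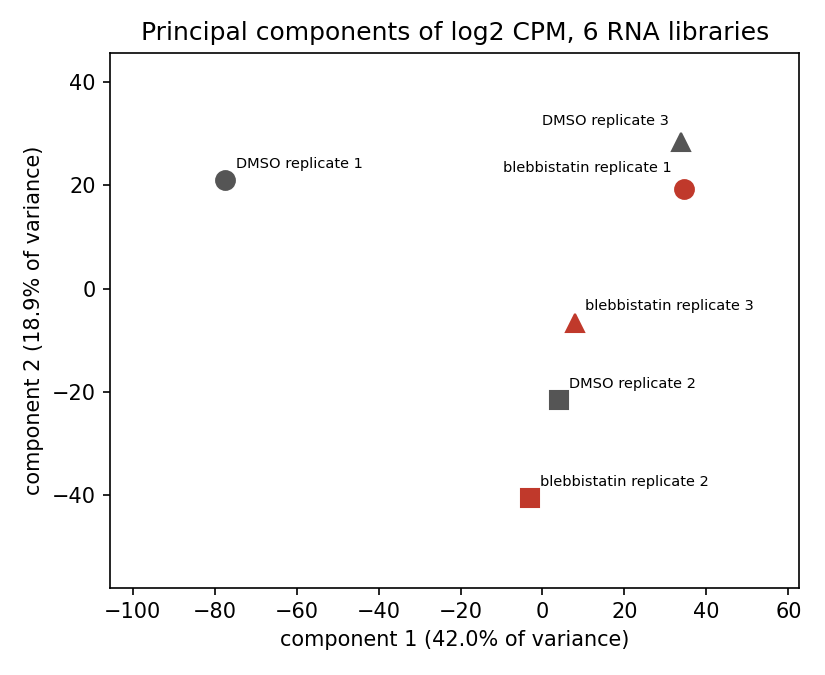
Principal components of the log2 CPM values of the 6 RNA libraries, component 1 (42% of the variance) on the horizontal axis and component 2 (18.9%) on the vertical axis, grey for DMSO and red for blebbistatin, with a marker shape per replicate number. DMSO replicate 1 lies at -77.4 on component 1, apart from the other 5 libraries.

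The immediate early genes are transcribed within minutes of a stimulus without new protein synthesis. Adjusted over the list alone, 11 of 43 measured members were lower after blebbistatin: Fos, Egr2, Plk2, Klf6, Dusp1, Zfp36, Btg2, Jun, Fosb, Arc and Egr3. Every list was adjusted in this way separately, without adjustment over the lists, and such counts were not in the design fixed beforehand. None was higher adjusted over the list alone. Over all 15204 genes tested, limma called 0 members, with 14 at an unadjusted p under 0.05, 13 lower and 1 higher. Of the 43 members, 32 had a negative and 11 a positive log2 fold change, with a median of -0.26. By replicate number, the list's mean log2 level was 4.9, 5.25 and 5.26 with DMSO and 4.8, 4.78 and 4.99 with blebbistatin. The groups overlapped in this mean.

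Fos, a subunit of the AP-1 transcription factor, had the lowest p of the list. It was at 27.5 ± 1.36 CPM with DMSO and 10.8 ± 0.79 CPM with blebbistatin (SD, n = 3 each). Its log2 fold change was -1.33 ± 0.14 (SE), with a limma adjusted p of 0.000671 over the list alone and 0.0593 over all genes. Egr2, a zinc finger transcription factor, was at 40.1 ± 4.75 and 17.8 ± 2.94 CPM, a log2 fold change of -1.17 ± 0.17. Klf6, another zinc finger factor, was at 85.8 ± 22.4 and 38.6 ± 3.01 CPM (-1.12 ± 0.19). Dusp1, a phosphatase of MAP kinases, was at 118 ± 21.5 and 62.7 ± 4.39 CPM (-0.90 ± 0.16). The polo-like kinase gene Plk2 was at 343 ± 20.9 and 210.3 ± 6.57 CPM (-0.70 ± 0.12). Egr1 and Ier5l did not pass, with log2 fold changes of -0.52 ± 0.18 and 0.62 ± 0.20 and limma adjusted p of 0.0715 and 0.0563 over the list alone. For 14 members all 3 treated libraries lay below all 3 controls and for 2 above, where chance gives 10% for both directions together.

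Camera with a preset correlation called the immediate early list lower (adjusted p = 6.72e-12). With an estimated correlation its p was 0.045 and its adjusted p = 0.823, and fry's test for change in a common direction gave an adjusted p of 0.558 and its test for change in either direction one of 0.00263. The count of 11 lower members was 5 without DMSO replicate 2, without blebbistatin replicate 1 or without blebbistatin replicate 2, and 16 without DMSO replicate 1.

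**Figure D2:**
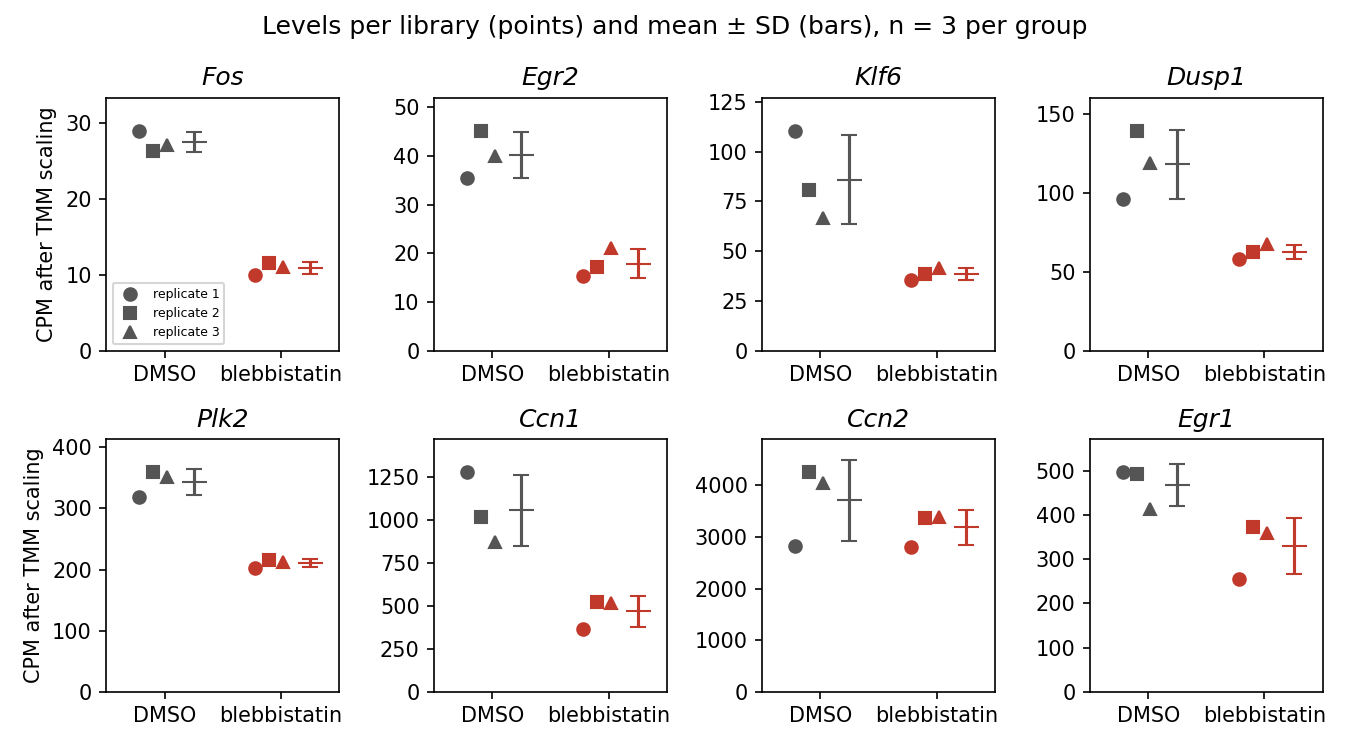
CPM after TMM scaling for 6 immediate early genes (Fos, Egr2, Klf6, Dusp1, Plk2 and Egr1) and the YAP and TAZ targets Ccn1 and Ccn2, with a point per library (shape by replicate number) and the mean ± SD of each group (n = 3) beside the points; every vertical axis starts at 0. All 3 blebbistatin libraries lie below all 3 DMSO libraries for each gene except Ccn2.

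Among the listed YAP and TAZ targets, genes that respond to tension and cell shape, Ccn1 (CYR61 in the table) was lower adjusted over the list alone. This secreted matricellular protein gene was at 1053 ± 207 CPM with DMSO and 468 ± 89.6 CPM with blebbistatin. Its log2 fold change was -1.17 ± 0.21, with a limma adjusted p of 0.0145 over the list alone and 0.765 over all genes. The other 23 members did not pass, among them Ccn2 (CTGF in the table; -0.20 ± 0.19), Amotl2 (-0.26 ± 0.12) and Ankrd1 (-0.11 ± 0.14). The list's median was -0.12, and 19 of 24 members had a negative fold change (camera adjusted p = 0.00616). In DMSO replicate 1 the list differed by 0.156 from the mean of the other libraries (0.0698 to 0.279 from each). Without that library its camera adjusted p was 0.00845 with the preset correlation. With an estimated correlation the adjusted p was 0.823, and fry's directional test gave 0.686. Without blebbistatin replicate 1 the preset correlation gave an adjusted p of 0.163, in a range of 0.00109 to 0.163 over the 6 left-out libraries.

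In the NF-kB and cytokine list, the interleukin 6 family cytokine gene Lif was lower adjusted over the list alone, with a log2 fold change of -0.68 ± 0.13 (limma adjusted p = 0.0273 over the list alone and 0.991 over all genes). Ptgs2, the inducible cyclooxygenase gene, had a log2 fold change of -0.52 ± 0.17 and did not pass. Camera did not call the list (adjusted p = 0.345, and adjusted p = 0.896 with an estimated correlation). Fry's directional test gave an adjusted p of 0.992 and its test for change in either direction one of 0.0243. Without DMSO replicate 1, camera with the preset correlation called the list lower (adjusted p = 0.000383); the estimated correlation was not run without that library.

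Camera with the preset correlation called 5 lists higher. With an estimated correlation none of the 5 was called (adjusted p = 0.823 for the oxidative stress and xenobiotic list and 0.896 for the other 4), and fry's directional test gave 0.558 and 0.992. In the interferon response list 20 of 24 members had a positive fold change, with a median of 0.28 (camera adjusted p = 0.000135). Oas1a and Mx2, antiviral effector genes, had log2 fold changes of 0.73 ± 0.26 and 0.57 ± 0.20. In DMSO replicate 1 this list differed by -0.58 from the mean of the other libraries. Without that library its camera adjusted p was 0.00845 with the preset correlation, in a range of 1.19e-06 to 0.022 over the left-out libraries. Oas1a and Mx2 were then at 0.59 and 0.384. In the oxidative stress and xenobiotic list 18 of 23 members were positive, with a median of 0.14 (camera adjusted p = 0.00188), and in DMSO replicate 1 the list differed by -0.205. Its camera adjusted p was 0.00845 without that library and ran from 0.00309 to 0.0194 over the left-out libraries, with the preset correlation. Cyp1a1, a cytochrome P450 gene induced through the aryl hydrocarbon receptor, had a log2 fold change of 1.02 ± 0.33 and Osgin1 one of 0.68 ± 0.22 (0.44 without DMSO replicate 1). In these 2 lists limma called 0 members, over all genes or adjusted over the list alone, with 3 and 2 at an unadjusted p under 0.05.

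The other 3 lists called higher were ribosomal protein genes (29 of 30 positive, median 0.22, camera adjusted p = 0.000266), oxidative phosphorylation genes (36 of 37 positive, median 0.16, adjusted p = 0.00147) and macrophage and leukocyte markers (10 of 12 positive, median 0.30, adjusted p = 0.0191). In DMSO replicate 1 these lists differed from the mean of the other libraries by -1.03, -0.69 and -0.89. Without that library their camera adjusted p was 0.791, 0.786 and 0.786, and the direction of the ribosomal and oxidative phosphorylation lists turned. Without blebbistatin replicate 1 the adjusted p was 0.413, 0.717 and 0.109, and without blebbistatin replicate 2 that of the macrophage markers was 0.0537. Over the 6 left-out libraries the values ran from 3.95e-09 to 0.791, from 3.95e-09 to 0.786 and from 0.0094 to 0.786.

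**Figure D3:**
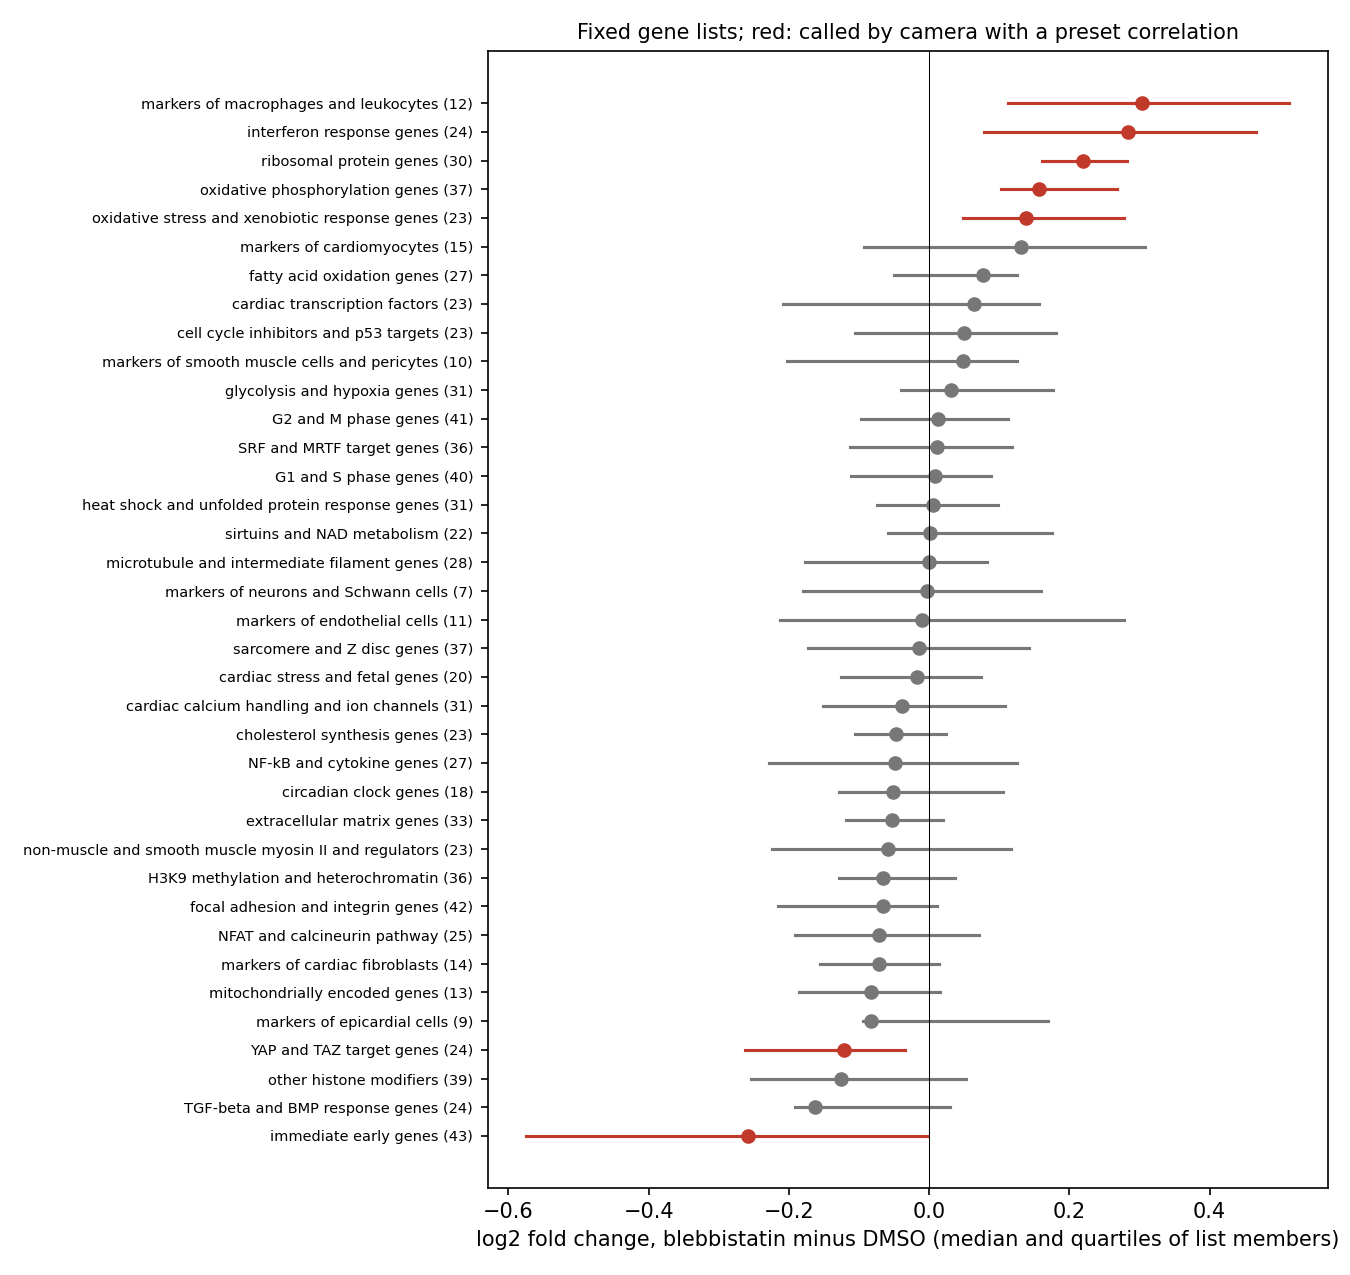
Log2 fold changes, blebbistatin minus DMSO, of the gene and marker lists reported that had at least 5 tested members, with a dot at the median of the measured members and a line between their quartiles; the number of members stands in brackets and red marks lists called by camera with the preset correlation. Of the lists shown, the immediate early list has the lowest median, -0.26, and the macrophage and leukocyte markers the highest, 0.30.

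The lists closest to the study's question were not called. For 25 genes of the NFAT and calcineurin list the median log2 fold change was -0.071 (camera adjusted p = 0.486). Nfatc1, Nfatc2, Nfatc3, Nfatc4 and Nfat5 had values of -0.13 ± 0.26, -0.19 ± 0.33, -0.19 ± 0.27, -0.092 ± 0.15 and -0.26 ± 0.31. Rcan1, a calcineurin inhibitor gene that responds to NFAT, was at 306 ± 47.3 and 319 ± 2.88 CPM (log2 fold change 0.071 ± 0.15). Over 22 genes of sirtuins and NAD metabolism the median was 0.0013 (camera adjusted p = 0.74). Over 36 genes of H3K9 methylation and heterochromatin it was -0.065 (0.182). Among the H3K9 methyltransferase genes, Suv39h1 (SUV39H1L1 in the table, a RefSeq synonym) had a log2 fold change of -0.061 ± 0.13, Suv39h2 one of 0.15 ± 0.29, Setdb1 one of -0.053 ± 0.15, Ehmt1 one of -0.17 ± 0.13 and Ehmt2 one of -0.11 ± 0.15. The G1 and S phase list (40 genes) and the G2 and M phase list (41 genes) had medians of 0.0085 and 0.013 (camera adjusted p = 0.957 and 0.997). Ccnd1 had a log2 fold change of -0.15 ± 0.14, Ccnb1 one of 0.11 ± 0.12, Cdk1 one of 0.29 ± 0.30 and Mki67 one of -0.37 ± 0.37.

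Cytoskeletal and sarcomere lists were not called either. The median was 0.011 over 36 SRF and MRTF targets (camera adjusted p = 0.949), with -0.18 ± 0.12 for Srf itself and 0.11 ± 0.16 for Acta1. This list shares no gene with the immediate early list, so its median does not cover Fos, Fosb or the Egr genes. It was -0.014 over 37 sarcomere and Z disc genes (0.957) and -0.059 over 23 genes of myosin II and its regulators (0.328). Over 20 cardiac stress and fetal genes it was -0.017 (0.95), with 0.96 ± 0.81 for Nppa and -0.046 ± 0.33 for Nppb. The myosin genes Myh9, Myh10, Myh14, Myh6, Myh7 and Myl2 had log2 fold changes of -0.41 ± 0.31, -0.21 ± 0.21, -0.19 ± 0.26, -0.17 ± 0.19, -0.24 ± 0.25 and 0.60 ± 0.36. Myh9 is uncertain, since the RefSeq names also assign MYH9L1 to it. MYH9L1, chosen after its values were seen, was listed at 0 in DMSO replicates 1 and 2, at 871.7 CPM in DMSO replicate 3 and at 795.9 to 1534 CPM in the treated libraries. Without DMSO replicate 1 the fold changes of Nfatc1, Nfatc2, Nfatc3, Nfat5, Rcan1, Setdb1, Ehmt2, Myh10, Myh14, Myh6, Myh7, Cdk1 and Mki67 took the opposite sign. The values of Nppa, Myh9 and Myl2 were then 0.015, -0.04 and 0.20.

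Over all 15204 genes tested, limma called 3 at an adjusted p under 0.05, 1 higher and 2 lower. Both lower genes, Rbm12, which encodes an RNA-binding protein, and LOC100910833, were listed at 0 in all 3 blebbistatin libraries. In the DMSO libraries Rbm12 was at 23.9, 24.1 and 20.9 CPM and LOC100910833 at 21, 20.9 and 18 CPM (limma adjusted p = 3.68e-05 for both). With zeros in the same libraries, these 2 genes may not be separate events. The table holds 106 genes at 5 CPM or more in a library and listed at 0 in another, and for 104 of them the zeros were split within a group. AC117058.1, which has no gene symbol, was at 0.239 ± 0.036 and 8.27 ± 3.70 CPM (log2 fold change 4.51 ± 0.40, limma adjusted p = 0.0335). It was not called without DMSO replicate 2, blebbistatin replicate 1 or blebbistatin replicate 2 (limma adjusted p = 0.178, 0.231 and 0.278). Over its alternatives the limma adjusted p ran from 0.00256 to 0.573, leaving out the default library weights. Those weights did not converge and gave 5.22e-05. LOC100910833 and AC117058.1 were chosen after their values were seen.

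Genes with symbols that came closest to the threshold on the higher side, without passing, were Rasd1, a Ras-related GTPase gene (log2 fold change 1.71 ± 0.22, limma adjusted p = 0.231), Aldh18a1, an enzyme gene of proline synthesis (2.52 ± 0.36, 0.334), and Capns1, the small subunit of calpain (1.16 ± 0.17, 0.334). Sgsm1 and Acat2l1 followed with 1.74 ± 0.36 and 0.92 ± 0.21 (both 0.991). The count of 3 genes was 6 without DMSO replicate 1, with Fos and Aldh18a1 among them, and 6 without DMSO replicate 3. At an unadjusted p under 0.05 there were 231 genes, 113 higher and 118 lower, where 760 would be expected by chance alone. The groups did not overlap for 932 genes, 6.13% against the 10% that chance gives.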

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

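The pseudocounts of 0.5 and 1 CPM, the restriction to genes above 0 in every library, both library weightings, and every alternative for the immediate early count and for single lists' camera p were chosen after seeing the data. The planned DESeq2, limma-voom and edgeR tests were not run, because the values are CPM. The 3 changed genes numbered 3 with RLE, library-size or upper-quartile scaling, with at least 1 CPM in 3 libraries and with robust=FALSE. They numbered 1 with only genes that have a symbol, and 0 (0 higher, 0 lower; 216 at an unadjusted p under 0.05 in limma) with only genes above 0 in every library, which drops both lower genes by construction. The 1 higher gene became 0 without a filter, at an adjusted p under 0.01 and with pseudocounts of 0.5 or 1 CPM. The 7 lists called by camera became 0 with an estimated correlation. Of the values of 64 named genes under the alternatives, 1069 kept their direction and side of the threshold, 43 passed it newly (32 of them with the default library weights, which did not converge), 8 no longer passed and 29 changed sign. Except where genes are dropped by construction, the cause was not tested.

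Library weights from limma's default estimator did not converge: DMSO replicate 2 got a weight of 43.9 and DMSO replicate 1 one of 0.129. The 706 genes then called (384 higher, 322 lower) and the 22 immediate early genes rest on nearly 1 control library and are not interpreted. Log2 fold changes changed sign for Nfatc4 (0.00122), Rcan1 (-0.0683), Suv39h1 (0.0143), Suv39h2 (-0.0842), Ehmt2 (0.0993), Myh14 (0.178) and Myh6 (0.0322). A gene-by-gene estimator, added after that result was seen, gave weights of 0.232 to 2.89, 13 genes (5 higher, 8 lower) and 14 immediate early genes, with Rcan1 at -0.0429, Ehmt2 at 0.0424 and Myh14 at 0.0998.

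With the replicate block 2 genes passed (0 higher, 2 lower) and 6 immediate early genes were lower instead of 11. Deviations of same-numbered libraries from their group means correlated at -0.29, 0.054 and -0.092. The highest correlation, 0.38, was between DMSO replicate 3 and blebbistatin replicate 1. These values give no sign that the numbers pair the samples. With 3 libraries per group and DMSO replicate 1 apart from the rest, they cannot exclude it.

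Leaving out each library in turn gave 3 to 6 changed genes, 0 to 4 higher, 2 to 3 lower, 3 to 9 lists and 5 to 16 immediate early genes. Camera adjusted p ran from 3.95e-09 to 0.786 for oxidative phosphorylation and from 3.95e-09 to 0.791 for ribosomal protein genes. Log2 fold changes that changed sign ran from -0.385 to 0.105 for Nfatc1, -0.468 to 0.134 for Nfatc2, -0.433 to 0.0883 for Nfatc3, -0.543 to 0.0708 for Nfat5, -0.0646 to 0.139 for Rcan1, -0.114 to 0.017 for Suv39h1, -0.126 to 0.396 for Suv39h2, -0.142 to 0.0657 for Setdb1 and -0.198 to 0.0173 for Ehmt2. They ran from -0.369 to 0.0241 for Myh10, -0.352 to 0.122 for Myh14, -0.273 to 0.0265 for Myh6, -0.432 to 0.0439 for Myh7, -0.0719 to 0.535 for Cdk1, -0.71 to 0.0592 for Mki67 and -0.439 to 0.247 for Nppb. Other values kept their sign but moved in size. From without DMSO replicate 1 to without DMSO replicate 3, they went from -0.212 to -0.0311 for Ankrd1, -0.0757 to -0.25 for Ehmt1, -0.0319 to -0.228 for Ccnd1, -0.0399 to -0.638 for Myh9, 0.199 to 0.851 for Myl2 and 0.0151 to 1.64 for Nppa. From without DMSO replicate 1 to without DMSO replicate 2, they went from -0.385 to -0.0912 for Ccn2, 0.44 to 0.801 for Osgin1 and 0.0471 to 0.149 for Ccnb1. Nfatc4 was at -0.176 without blebbistatin replicate 3 and -0.00151 without blebbistatin replicate 2, and Acta1 at 0.043 without blebbistatin replicate 2 and 0.25 without blebbistatin replicate 1.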

Other observations

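All tests of explanations and all counts of splits in this part were chosen after the results were seen; the gene lists were fixed before. Several signalling genes outside the rule for named genes, chosen after their values were seen, had separated groups without passing over all genes (limma adjusted p = 0.991 for each). Hes1, a Notch target, was at 24 ± 8.37 and 52.6 ± 6.10 CPM (log2 fold change 1.19 ± 0.28), and Edn1, the endothelin-1 gene, at 60.8 ± 21.4 and 31.8 ± 3.05 CPM (-0.87 ± 0.27). Inhba, an activin subunit gene, had a log2 fold change of -0.67 ± 0.21 and Errfi1, an inhibitor of the EGF receptor, one of -0.48 ± 0.14. From the lists, the TGF-beta decoy receptor gene Bambi had 0.68 ± 0.22, the mTOR inhibitor gene Ddit4 0.84 ± 0.23, the intermediate filament gene Nes -0.67 ± 0.25 and the ventricular transcription factor gene Irx4 0.36 ± 0.14; none passed (limma adjusted p = 0.991 for each). Without DMSO replicate 1 the log2 fold changes of Hes1, Inhba, Bambi, Ddit4, Nes and Irx4 were closer to none: 0.86, -0.43, 0.44, 0.57, -0.39 and 0.30. Those of Edn1 and Errfi1 were then larger in size, -1.19 and -0.60. Separated groups were found for 6.13% of all genes tested, where chance gives 10%.

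With all 6 libraries, camera called none of the following lists. The median log2 fold change was -0.16 for TGF-beta and BMP response genes (mean -0.026; adjusted p = 0.374), -0.12 for other histone modifiers (0.126), -0.065 for focal adhesion and integrin genes (0.0816) and -0.053 for extracellular matrix genes (0.182). Leaving out a library brought calls, all lower, for other histone modifiers without DMSO replicate 3 (0.0113), for focal adhesion and integrin genes without DMSO replicate 3 (0.0113) or blebbistatin replicate 3 (0.017), and for mitochondrially encoded genes without blebbistatin replicate 2 (0.00662). With all libraries and an estimated correlation the adjusted p of these 3 lists was 0.896, 0.896 and 0.908. The median was 0.031 for glycolysis and hypoxia genes (0.533), 0.077 for fatty acid oxidation genes (0.426), -0.082 for mitochondrially encoded genes (0.345), -0.047 for cholesterol synthesis genes (0.426) and 0.0052 for heat shock and unfolded protein response genes (0.957). It was 0.05 for cell cycle inhibitors and p53 targets (0.95), 0.064 for cardiac transcription factors (0.957), -0.038 for calcium handling and ion channels (0.957), -0.052 for circadian clock genes (0.661) and 0.00033 for microtubule and intermediate filament genes (0.753). Among markers it was 0.13 for cardiomyocytes (0.345), -0.072 for fibroblasts (0.345), -0.01 for endothelial cells, 0.048 for smooth muscle cells and pericytes, -0.083 for epicardial cells and -0.0024 for neurons and Schwann cells (0.957 for these 4). The 4 red blood cell genes measured had a median of -0.55 and were not tested as a list. Hba-a2 was at 112.8 CPM in DMSO replicate 1 and at 33.8 to 42.6 CPM in the other libraries.

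The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 3 changed genes (as many in 3 splits, highest other 5), 1 higher (as many in a direction in 8 splits, highest other 3), 2 lower (6 splits, highest other 3), 7 lists (2 splits, highest other 9) and 11 immediate early genes adjusted over the list alone (1 split, highest other 0). The split that set DMSO replicate 1 and blebbistatin replicates 1 and 2 against the rest gave the immediate early list a camera p of 1.33e-12 and a mean log2 difference of 0.34, against 1.77e-13 and 0.28 for the real split, so the list's camera p alone says little about blebbistatin. The split of DMSO replicates 1 and 2 and blebbistatin replicate 2 against the rest had 3067 genes at an unadjusted p under 0.05, against 231, which points to a structure of the samples.

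For the lower immediate early genes, DMSO replicate 1 had the lowest list mean of the controls, 4.9 against 5.25 and 5.26. Leaving it out could therefore only widen the gap in list means, so the 16 lower members without it are no test of that library. Its mean lay nearest to the treated libraries (4.8, 4.78 and 4.99). That argues against it as the cause of the list's lower mean. A smaller share of another cell type in the treated dishes is argued against for the 6 other types with at least 5 measured markers, whose lowest median log2 fold change was -0.0833, while the 11 lowered genes had a median of -0.83. Those 11 were chosen for being lower in these data, and the whole list had a median of -0.258. The lowest lower quartile among these marker lists was -0.212, for endothelial cells, so the contrast with the whole list is smaller. Fewer red blood cells are argued against by Hba-a2 and Hbb, which had log2 fold changes of -0.62 and -0.53 with all libraries but -0.0886 and -0.0442 without DMSO replicate 1. There the mean log2 fold change of the whole immediate early list was -0.401. Of the 11 early genes, 10 were again lower there, but they had been chosen from data that include these same libraries. A difference in handling or harvest time between dishes could also lower these genes and stays open, since 0 RNA libraries carry a label for batch, date, order or harvest. An effect of blebbistatin is therefore a hypothesis that cannot be told apart from handling here.

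For DMSO replicate 1, a single scaling factor is argued against, since other histone modifiers minus ribosomal protein genes differed by 1.36 from the mean of the other libraries and by 1.05 to 1.7 from each of them. These 2 lists lay near opposite ends of the ranking of lists, so the choice favoured a gap. Against each other library the ribosomal protein genes differed by -1.31 to -0.775 and the other histone modifiers by 0.278 to 0.401. A lower share of cardiomyocytes would tend to raise the markers of the other types. Macrophage and leukocyte markers differed by -0.887, neuron and Schwann cell markers by -0.194, endothelial markers by -0.0677 and fibroblast markers by -0.011. Epicardial markers differed by 0.0396 and smooth muscle and pericyte markers by 0.112. Each type's share can also vary on its own, and an effect of transcript length was not separated, so these values cannot decide. RNA integrity or fragment selection may contribute and stays open: the short ribosomal protein transcripts differed by -1.03, and gene lengths of the build are not used here. Beyond the share of cardiomyocytes, no biological explanation was tested.

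For the 106 genes listed at 0 in a library and at 5 CPM or more in another, the treatment is argued against for the set, since 104 had zeros split within a group. Zeros placed without regard to treatment stay open for the other 2, Rbm12 and LOC100910833: 12 genes had 3 zeros, 1.2 of them would fall on a whole group by chance, and 2 did (exact binomial p = 0.341). That test assumes independent genes, but the 12 genes showed only 8 patterns of zeros. Rbm12 and LOC100910833 shared a pattern and may not be separate events, so this p cannot decide. Reads moved between overlapping gene models could also give such zeros. Of those with a RefSeq position 45.7% overlapped another gene model, against 43.4% of other genes at 5 CPM or more, but only 33% had a position, so that test is void.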
